A study of Mus musculus with 3 samples.

How the data were processed

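Whole prostates of C57BL6 mice of 12 to 15 weeks were measured by droplet single-cell RNA sequencing (10x Genomics), with 1 library from Srd5a2 knockout and 2 libraries from Srd5a2 heterozygous tissue. Groups were taken from the genotype labels, and replicate numbers only name the samples. The values deposited for each library are raw UMI counts per gene and barcode, whole numbers with no normalization, made with Cell Ranger 3.1.0 on mm10 per the submitters' processing notes. How barcodes were called as cells, the chemistry and the number of animals per library are not given in the sources used here. Each matrix lists the same genes, and gene coordinates are from GENCODE vM21. Totals were 129015041, 47601747 and 100801564 UMIs in 13273, 5000 and 13866 barcodes (knockout, heterozygote 1, heterozygote 2). Heterozygote 1 has a higher lowest barcode total (2466 UMIs) than the others (586 and 500), so shallow barcodes are compared between the knockout and heterozygote 2.

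Barcodes with at least 500 genes and at most 15% mitochondrial UMIs were kept (9983, 4718 and 10587). Doublets were scored with scrublet as built into scanpy 1.11.5. Its automatic threshold called 0%, 0% and 0.0163%, under a floor of 0.5%, so the top-scoring share equal to a rate of 0.8% per 1000 cells was called (expected 9.77%, 3.95% and 9.80% of barcodes under the looser filter; called 9.995%, 4.51% and 10.2% with tied scores). This removed 1006, 219 and 1085 of the barcodes kept. The 8977, 4499 and 9502 cells left held 111307657, 44149987 and 83015293 UMIs. The libraries were clustered together, without batch correction, on 2000 variable genes, 30 principal components, 15 neighbors and Leiden resolution 1.0 (igraph 0.11.9). Leiden borders proved sensitive to the last digits of the neighbor distances, which depend on the arithmetic kernel of the linear algebra library. A repeat with another kernel gave other clusters, as did distances from whole-number coordinates and rounded neighbor weights, which were tried and not carried further, so the kernel of the clustering made at the start was set, and that clustering was kept because the cluster tests had been written on it. Values under the other kernel and another random seed are given as alternatives. Left out of clustering were 83 genes that each took at least 0.1% of UMIs in barcodes under 500 genes, which keeps secretory RNA shared by all droplets from driving the clusters. Clusters were named by marker lists written before the data were examined, a marker counting as detected at a log2 fold of 1.0 over the other cells and in 25% of cells, with at least 3 detected for a name. Seminal vesicle-like cells carry that name on markers alone. Lymphatic, B cell, neutrophil and other small classes formed no cluster of their own.

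UMIs were summed per library over the cells of a class, and a class was fitted only with at least 50 cells in each library. This gave luminal (secretory and proximal together), basal, fibroblast, smooth muscle, endothelial and macrophage classes. Genes were tested with edgeR 4.0.16 (filterByExpr, TMM scaling, quasi-likelihood fit), Benjamini-Hochberg adjusted over all genes tested, at a threshold of 0.05. The design leaves 1 residual degree of freedom. As a reference the same fit was run with each heterozygote as the lone library. That fit takes the knockout and the other heterozygote as replicates, so a real knockout difference widens its spread and lowers its calls. The 3 possible splits give a smallest share of 0.33, so regrouping the libraries cannot show whether chance gives as many genes. CPM of the steroid genes fixed in advance use plain totals, and those of other genes TMM-scaled totals. Differences against each heterozygote use log2 CPM with a prior count of 2. Where a group had no UMIs, the fold is a lower bound against a floor of 3 UMIs over the group; with 1 to 3 UMIs it is a ratio with an exact 95% interval. Intervals and floors cover counting error only. Shares of cells carry exact Clopper-Pearson 95% intervals. For the share of luminal cells with an Esr1 UMI, each cell was thinned to 1000 UMIs, from the 10th percentile of the shallowest library, and 6, 0 and 146 shallower cells were left out.

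Gene lists, 23 in number, were fixed before the data were examined, and so were the tests, the classes and most alternatives. They cover androgen and estrogen response, steroid enzymes and receptors, secretion of prostate and seminal vesicle, proximal luminal identity, stress, immune, growth, metabolic, matrix and contractile programs. They were tested with camera in limma 3.58.1 on log2 CPM with a preset correlation of 0.01, adjusted over the lists of a class. With that preset the p-values set a list against the spread over genes, taken as nearly independent. They do not measure the spread between libraries. The test was repeated with an estimated correlation. That form has 1 residual degree of freedom here, so a list could hardly pass however large its shift. Medians were also set against 10000 random lists matched on expression over 20 bins. The named genes follow a rule also fixed then. Among genes past the threshold, ranked by the smaller of the knockout's differences from each heterozygote, the 10 highest and 10 lowest were taken in luminal cells and the 5 highest and 5 lowest in other classes. Missing places were filled from genes with a mean of at least 10 CPM that did not pass. Mitochondrial, ribosomal, hemoglobin and predicted genes were left out of that ranking, and outside luminal cells so were secretory genes and markers of other types. Fixed steroid genes and the top members of each list were named too. Some of the genes these rules picked are not reported here. Other genes, among them Rrp1b, Jund and the ribosomal proteins, were chosen after their values were seen.

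Alternatives fixed in advance were median-ratio size factors, DESeq2 1.42.0, no filter on low counts, limma-voom, doublets kept, a looser filter (200 genes, 25% mitochondrial), a stricter filter (1000 genes, 10% mitochondrial), UMIs thinned to equal class totals, secretory or proximal clusters alone, thinning to 2000 UMIs or none for the Esr1 share, and each heterozygote left out. Leiden resolutions 0.5 and 2.0 were fixed in advance for Esr1, shares and luminal lists. Added after seeing the data were those resolutions for genes changed, another random seed and another arithmetic kernel for the clustering, subtraction of seminal vesicle-like and luminal RNA in proportion to marker genes, luminal clusters whose median cell has under 1% seminal vesicle RNA, class shares among cells of at least 2466 UMIs and without cluster 9, tests in single clusters, list tests on thinned counts, and the second luminal gene ranking.

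The tests were checked on simulated data with the same library sizes, a biological coefficient of variation of 0.1 and 200 changed genes. In luminal cells edgeR recovered 65.7%, 95.5% and 98.5% of genes changed by a log2 size of 1, 2 and 4, with 11 unchanged genes among 184 called. DESeq2 recovered 47.8%, 77.6% and 83.3% with 2 unchanged among 141, and limma-voom 62.7%, 94.0% and 98.5% with 18 among 188. In the other classes edgeR recovered 59.7% to 70.1% at a size of 1 and 91.0% to 98.5% at a size of 2. The simulated spread was the same for every gene and class, and changes were placed only in well-counted genes. These shares therefore do not give the power in the real data. Of 23 lists, the shifted one alone passed (adjusted p = 1.26e-33). Simulated genes were drawn independently of each other, so the list check could not show false calls from correlated genes. Python 3.11.15, anndata 0.12.19, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, matplotlib 3.10.9 and R 4.3.3 were used.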

Results

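Srd5a2 encodes steroid 5α-reductase type 2, which turns testosterone into the stronger androgen dihydrotestosterone. Cells of whole mouse prostate were compared between 1 Srd5a2 knockout library and 2 Srd5a2 heterozygote libraries, all from C57BL6 mice of 12 to 15 weeks, with attention to luminal cells that carry estrogen receptor alpha (Esr1). Per the labels, every tissue was digested for 2 h at 37 °C in a buffer that contained dihydrotestosterone, so the levels of androgen-regulated transcripts were read after that exposure. Of 13273, 5000 and 13866 deposited barcodes (knockout, heterozygote 1, heterozygote 2), 8977, 4499 and 9502 were kept as cells, with a median of 4389, 7016 and 5026.5 unique molecular identifiers (UMIs) per cell. Heterozygote 1 held no barcode under 2466 UMIs, while the lowest values were 586 in the knockout and 500 in heterozygote 2. Log2 fold changes are knockout minus heterozygote, ± standard error, from 1 against 2 libraries, and adjusted p-values are edgeR's unless another tool is named. These p-values rest on the spread between the heterozygote libraries, largely shared over genes because 1 residual degree of freedom is left. A gene can therefore pass without differing from both heterozygotes. Cebpb in basal cells was called lower at 0.34 against heterozygote 1 and -2.42 against heterozygote 2. The lone knockout library is assumed to vary like the heterozygotes, and the labels do not say how many animals each library holds.

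Srd5a2 itself (ENSMUSG00000038541.8, mm10 chromosome 17, 74016955 to 74047916, minus strand) was found in the stroma, and the knockout's stroma had almost none of it. Fibroblasts held 1 Srd5a2 UMI in the knockout, against 29 in heterozygote 1 and 44 in heterozygote 2, which is 0.724 against 138 and 104 CPM (UMIs scaled to a common library total). The level was 159-fold lower in the knockout (95% counting interval 27.6 to 6361, adjusted p = 1.51e-18), although limma-voom did not call it. Smooth muscle held 3 UMIs against 55 and 54, a level 74.3-fold lower (24.8 to 366) that did not pass with edgeR's TMM scaling (adjusted p = 0.161) and did pass under 12 other settings, DESeq2 among them. Luminal cells held 3, 8 and 15 UMIs, endothelial cells 0, 0 and 2, and basal cells and macrophages none in any library, which allows up to 3 UMIs in each library. The labels do not say which part of the gene was deleted, so remaining transcripts are not evidence of enzyme. Transcripts of the other family members did not change detectably in luminal cells. Srd5a1 moved by -0.07 ± 0.48 (adjusted p = 0.995) on 32, 53 and 68 UMIs, and Srd5a3 by -0.23 ± 0.31 (adjusted p = 0.945).

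Secretory luminal cells, which make the prostate's fluid, were a smaller share of the knockout library, and seminal vesicle-like epithelial cells a larger one. Luminal secretory clusters held 18.2% of knockout cells (exact 95% interval 17.4 to 19.0%) against 47.5% and 49.5% of heterozygote cells. Clusters named seminal vesicle-like, each on at least 3 of 7 markers of that neighbouring gland (such as Svs2, Svs4, Svs5 and Pate4), held 29.1% (28.2 to 30.1%) against 14.8% and 9.32%, or 19.3% against 14.8% and 9.26% without cluster 9. Stroma was also larger in share, with fibroblasts at 5.69% against 1.40% and 2.36%, smooth muscle at 6.65% against 2.89% and 2.12%, and endothelial cells at 3.799% against 2.05% and 1.34%. Proximal luminal cells were at 1.31% against 7.65% and 2.79%. T or NK lymphocytes, in few cells, were at 2.72% (2.39 to 3.08%) against 0.289% and 0.768%. Basal cells differed little, at 13.1% against 13.6% and 14.04%, and the acid-secreting ionocytes lay between the heterozygotes at 2.35% against 2.45% and 2.25%. Macrophages were at 1.82% against 1.20% and 1.28%, glial cells at 0.434% against 0.044% and 0.242%, and cells in unnamed clusters at 14.8% against 6.18% and 14.01%. Since heterozygote 1 held no shallow barcodes, its shares of low-depth classes are not on the same footing. Among cells of at least 2466 UMIs, a comparison added after seeing the data, T or NK cells were at 2.44% against 0.289% and 0.059%, fibroblasts at 4.37% against 1.40% and 0.531%, glial cells at 0.131% against 0.044% in both, and basal cells moved above both (14.8% against 13.6% and 10.8%). The knockout lay outside both heterozygotes in 10 of 11 named classes, where chance alone puts it outside in 67%, and in 8 of 11 with another random seed for the clustering. Endothelial cells then lay between the heterozygotes (1.42% against 1.56% and 1.11%), as they did at Leiden resolutions 0.5 and 2.0 and with another arithmetic kernel. Shares add up to the whole library, so a surplus of one class lowers the others, and no test across libraries was made because an exact permutation test of 1 against 2 cannot go below 0.33.

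**Figure D1:**
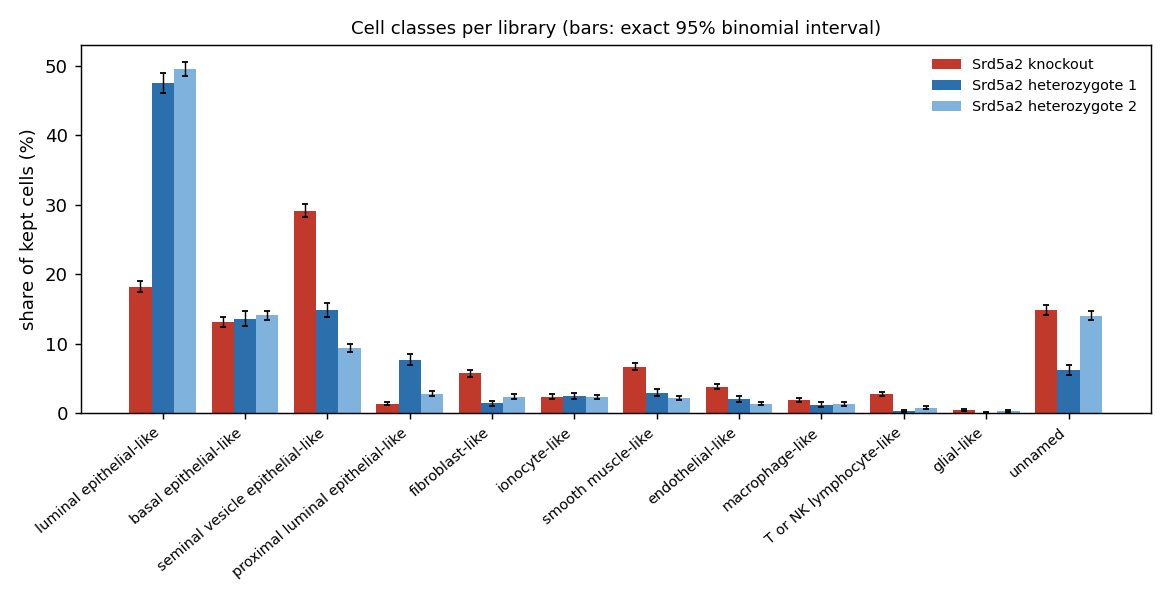
Share of kept cells in each cell class (y axis, percent) in the knockout and both heterozygote libraries, with exact 95% binomial intervals. Secretory luminal cells were at 18.2% in the knockout against 47.5% and 49.5%, and seminal vesicle-like cells at 29.1% against 14.8% and 9.32%.

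Of the clusters named seminal vesicle-like, clusters 9 and 11 were found almost only in the knockout. Heterozygote 2 likewise held most cells of unnamed cluster 17 (39, 14 and 523 in the knockout, heterozygote 1 and heterozygote 2). The same held for luminal clusters 19 (12, 41 and 484) and 23 (1, 17 and 350). A cluster found mainly in 1 library is therefore not by itself a trait of the genotype. Cluster 11 held 802, 7 and 5 cells (knockout, heterozygote 1, heterozygote 2), with Sva, Ceacam10, Svs3a and Svs3b as leading genes, a median of 52044 UMIs and 80.0% of UMIs from the seminal vesicle secretory list. Cluster 9 held 879, 1 and 6 cells, 9.79% of knockout cells, at a median of 2433 UMIs. It was named on Svs1, Svs3a, Svs4 and Svs6, but none of its 10 leading genes was a seminal vesicle marker. Its median cell had 19.5% of UMIs from the list, less than the 26.3% of UMIs in knockout barcodes under 500 genes. Clusters 5 and 13 held cells of all 3 libraries, 490, 298 and 483 cells in cluster 5 and 309, 325 and 132 in cluster 13. RNA of these secretory genes was also found outside those cells. It made up 44.5% of all knockout UMIs against 14.8% and 12.5%. Svs5 was seen in nearly every barcode of each library: all 13273 in the knockout, 4985 of 5000 in heterozygote 1 and 13851 of 13866 in heterozygote 2. Within luminal cells the list took 3.65% of knockout UMIs against 0.652% and 1.74%, and within basal cells 4.21% against 0.513% and 0.990%. The luminal value depended on the cells taken: the knockout lay below heterozygote 2 with the looser filter (2.56% against 2.74%), with the stricter filter (2.67% against 2.76%) and at Leiden resolution 0.5 (2.08% against 2.59%). In basal cells, fibroblasts and macrophages the knockout was above both in every setting that gave a value, before subtraction.

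**Figure D2:**
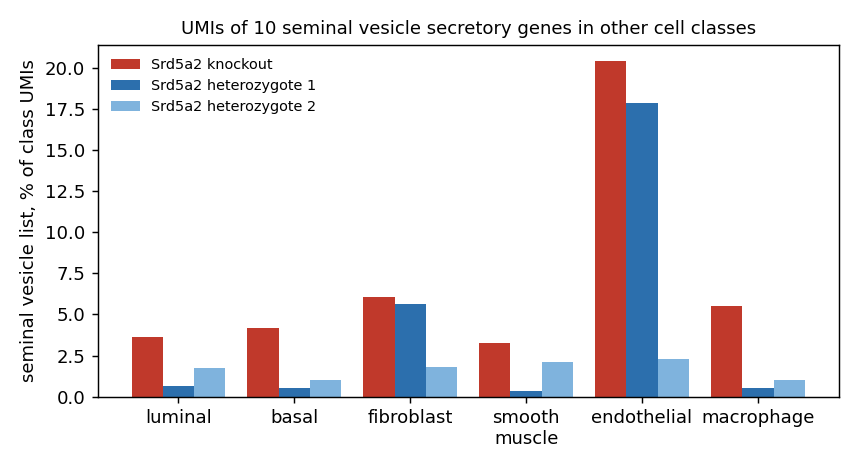
Percent of each class's UMIs (y axis) that came from 10 seminal vesicle secretory genes, by cell class and library. The knockout was above both heterozygotes in each of the 6 classes, from 3.26% in smooth muscle to 20.4% in endothelial cells. That order did not hold in endothelial cells with another clustering (7.35% against 12.5% and 1.90% with another random seed) or in smooth muscle with the stricter filter (2.96% against 0.321% and 3.03%).

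Several transcripts of secreted proteins were lower in knockout luminal cells, and RNA of seminal vesicle products was higher in them under the clustering used. Secretoglobins, small secreted proteins, led the decrease. Scgb2b7 was 674-fold lower (95% counting interval 121 to 26620; 1 UMI against 801 and 1728), Scgb2b20 at least 106-fold, Scgb1b20 at least 54.8-fold and Scgb2b12 at least 15.5-fold lower, each bound against a floor of 3 UMIs over the group. Crisp1, a secreted sperm-binding protein, was at least 58.5-fold lower (0 against 258 and 401 UMIs). Several of these came from few cells, since cluster 16, which held 55, 252 and 311 cells, carried 77.9% of all Scgb2b7 UMIs. The lipocalin Mup4 decreased by 6.68 ± 0.60 (adjusted p = 8.88e-07), but 95.9% of its UMIs came from cluster 28, and it did not pass among secretory clusters alone or with the stricter cell filter. Mug1 was 78.9-fold lower (26.9 to 383) and Syt4 78.9-fold lower (14.04 to 3125), Snap25 decreased by 5.25 ± 0.55 (adjusted p = 7.72e-06), and the trefoil peptide Tff3 was at least 48.1-fold lower with all of its heterozygote UMIs in 2 and 5 cells. Syt4 and Snap25, parts of the vesicle release machinery, came mainly from cluster 6, which carried 93.9% and 91.5% of their UMIs.

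In all, 232 of 17153 genes differed in luminal cells (91 higher, 141 lower; 1781 at an unadjusted p under 0.05), where the same test called none with heterozygote 1 or heterozygote 2 as the lone library (371 and 924 at an unadjusted p under 0.05). Those reference fits, in every class, count the knockout as a replicate of the other heterozygote. Few calls there are therefore not a like-for-like baseline. Another random seed or arithmetic kernel for the clustering gave 337 and 357 genes, of which 201 and 188 were among the 232. The count ran from 142 with DESeq2 to 538 with median-ratio size factors. With limma-voom 203 passed, 53.7% of them higher against 39.2% here. The 10 genes named on the higher side were the seminal vesicle genes Svs1, Svs3a, Svs3b, Svs4, Svs6 and Sva, together with Ceacam10, Dnase2b, Scgb1b27 and Scgb2b27. Svs6 increased by 5.60 ± 0.34 (adjusted p = 1.54e-09), Ceacam10 by 3.99 ± 0.51 (adjusted p = 1.32e-04) and Scgb1b27 by 8.09 ± 0.42 (adjusted p = 1.29e-10). In the knockout, 97.8% of luminal Scgb1b27 UMIs and 97.6% of Scgb2b27 UMIs came from 10 cells. Subtracting RNA of seminal vesicle-like cells turned Ceacam10, Svs3a, Svs3b and Sva to lower, and Scgb2b27 turned to lower in secretory clusters alone and with the stricter cell filter.

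Genes spread over many luminal cells were ranked by a second rule, added after the data were seen. It kept 41 genes with one direction in clusters 2, 3 and 4, under 50% of their UMIs in 10 cells and a mean of at least 10 CPM, that were also called after subtraction of foreign RNA and in luminal clusters low in seminal vesicle RNA. Igfbp7, which binds insulin-like growth factors, fell by 2.54 ± 0.35 (adjusted p = 0.0003), the matrix metalloproteinase Mmp7 fell by 1.57 ± 0.32 (adjusted p = 0.0114; 858 CPM against 2508 and 2593), and the metalloproteinase inhibitor Timp2 fell by 1.73 ± 0.30. The protease inhibitor Spink1 fell by 1.78 ± 0.31, the stress-induced Nupr1 by 1.93 ± 0.35 and the secretory-pathway transcription factor Creb3l1 by 1.97 ± 0.32. On the higher side, tissue plasminogen activator (Plat) rose by 1.37 ± 0.27 (adjusted p = 0.0078), the gluconeogenic enzyme Fbp1 by 1.38 ± 0.26, the lipid transfer protein Pitpnc1 by 1.69 ± 0.28 and the heat shock protein Hspa1a by 1.28 ± 0.28 (adjusted p = 0.0194). Rrp1b (chromosome 17, 32036100 to 32062865), a nucleolar protein, rose by 1.67 ± 0.29 (adjusted p = 0.0032; 874 CPM against 269 and 282), and it passed in basal cells (1.39), endothelial cells (2.09) and macrophages (1.27) as well. Rrp1b, Hspa1a, Fkbp5, Tff3 and Crisp1 lie on chromosome 17, as Srd5a2 does, and whether the targeted chromosome carries a segment of another strain was not analysed here. Rrp1b, Pitpnc1, Plat and Hspa1a kept their call in every setting that took luminal clusters together, including the subtraction and the clusters low in seminal vesicle RNA, which the rule itself required, while Nupr1 and Creb3l1 turned positive in proximal clusters taken alone (0.56 and 0.71). In single clusters Plat rose mainly in cluster 3 (2.65), with 0.22 (adjusted p = 0.922) in cluster 2 and 0.36 (adjusted p = 0.788) in cluster 4, and Hspa1a was at 0.24 (adjusted p = 0.917) in cluster 3. Timp2 passed in none of clusters 2, 3 and 4 (-1.53, -1.15 and -0.40; adjusted p = 0.131, 0.38 and 0.949). Nupr1 was at -4.26, -4.72 and -3.78 there, further from 0 than in all luminal cells, where cluster 16 held 59.4% of its UMIs.

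Esr1 transcript in luminal cells was somewhat higher in the knockout, within the error of the test. Esr1 (ENSMUSG00000019768.16, chromosome 10, 4611593 to 5005614, plus strand) stood at 104 CPM in the knockout against 76.1 and 77.6, a log2 fold change of 0.44 ± 0.28 (adjusted p = 0.701), with values of 0.43 and 0.46 against each heterozygote. After thinning each luminal cell to 1000 UMIs, Esr1 was seen in 10.9% of knockout cells (exact 95% interval 9.51 to 12.5%; 191 of 1746), 7.42% (6.42 to 8.52%; 184 of 2480) and 7.74% (6.998 to 8.53%; 373 of 4821) of heterozygote cells. Unthinned shares were 49.6%, 43.5% and 42.9%, at median depths of 10079, 9279 and 8846 UMIs. As background, at the same thinned depth macrophages had Esr1 in 1.23%, 1.85% and 1.64% of cells. T or NK cells had it in 2.08%, 15.4% (2 of 13 cells) and 1.45%, at median depths of 2766, 3686 and 1581 UMIs. The luminal difference was widest in cluster 14, led by Msmb, Wfdc3 and Defb50, with 19.5% against 7.59% and 8.14%, and in cluster 2, led by Scin and Ren1, with 16.9% against 9.46% and 12.5%. In cluster 4 the knockout lay between the heterozygotes (7.69% against 9.06% and 7.44%), and proximal cells were near background in all libraries (2.54%, 2.33% and 1.53%). The gap between the knockout and the heterozygote mean in the share of luminal cells with an Esr1 UMI, 3.36 percentage points, was 0.799 with doublets kept, 1.23 and 1.64 with the looser and stricter cell filters and 1.20 at Leiden resolution 2.0. With another random seed for the clustering it was 0.462, from 7.79% against 7.58% and 7.08%, and with another arithmetic kernel 2.65. The size of the gap thus depends on which cells are counted as luminal.

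Progesterone receptor, a well-known estrogen receptor target, rose in luminal cells. Pgr (ENSMUSG00000031870.16) rose by 1.95 ± 0.39 (adjusted p = 0.0099), from 2.02 and 1.22 CPM in the heterozygotes to 6.11 in the knockout, on 55, 62 and 127 UMIs. The call ended with DESeq2 and with doublets kept, and direction held. Fkbp5, an androgen- and glucocorticoid-induced chaperone, was lower by a margin that just missed the threshold, at -1.16 ± 0.30 (adjusted p = 0.0644; 32.6 CPM against 80.2 and 66.1), and it passed in 14 other settings. The androgen-regulated probasin (Pbsn) was at -0.02 (adjusted p = 0.997). Esr2 moved by -0.30 (adjusted p = 0.954).

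**Figure D3:**
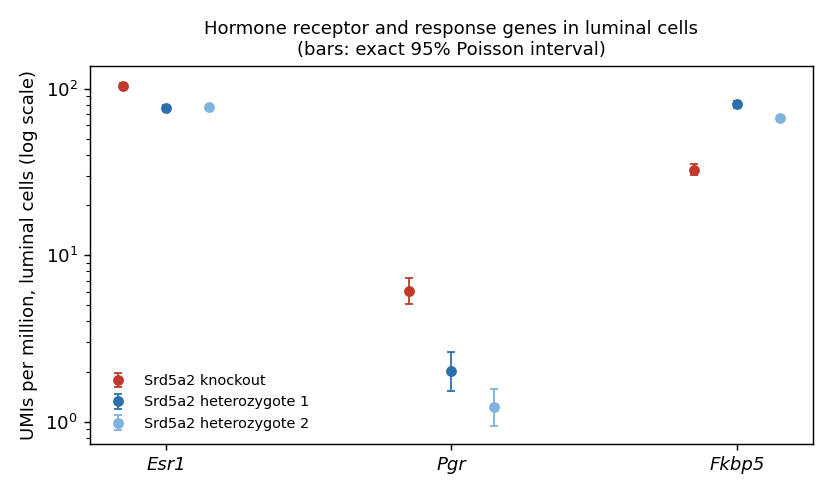
Level of hormone receptor and response genes in luminal cells (y axis, CPM on a log scale) in each library, with exact 95% Poisson intervals. Pgr stood at 6.11 in the knockout against 2.02 and 1.22, and Fkbp5 at 32.6 against 80.2 and 66.1.

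Knockout luminal cells had lower cell division and cholesterol synthesis transcripts. Of 24 cell cycle genes, 5 fell and none rose (11 passed adjusted over the list alone), with a median of -0.82 and camera adjusted p = 5.14e-12; Mki67 fell by 3.38 ± 0.54 (7 UMIs against 89 and 196), Birc5 by 2.45 ± 0.50 and Ube2c by 2.43 ± 0.50, and Cenpf had 3 UMIs against 90 and 177. Of 23 cholesterol synthesis genes, 1 fell and none rose (8 adjusted over the list alone), with a median of -0.62 and adjusted p = 2.16e-07; 22 were below both heterozygotes, among them the sterol carrier Stard4 (-1.35 ± 0.32, adjusted p = 0.0319). Among 15 prostate secretory products, Sbp, Sbpl and Spink1 fell (4 adjusted over the list alone; median -0.29, adjusted p = 0.00222), Sbpl by 2.18 ± 0.40. Of 21 proximal or castration-resistant luminal genes, Ppp1r1b and the retinal dehydrogenase Aldh1a1 fell (6 adjusted over the list alone; median -0.56, adjusted p = 0.00941), a call that ended with doublets kept. Of 24 oxidative stress defence genes, the glutathione transferases Gsta3 and Gstp1 fell, each by 1.68 ± 0.32 (3 adjusted over the list alone; median -0.31, adjusted p = 0.0217). The 26 interferon-stimulated genes lay higher as a set (median 0.47, adjusted p = 0.00809) although none passed singly or adjusted over the list alone, and the call ended at Leiden resolution 0.5 and on subtracting foreign RNA. The same held for 20 contractile genes (median 0.40, adjusted p = 0.0217), which rested on heterozygote 1: the median was 0.95 against heterozygote 1 and -0.11 against heterozygote 2. That call ended with another random seed and another arithmetic kernel for the clustering, and the oxidative stress call ended with the other seed. The seminal vesicle list, where 6 of 10 genes rose and none fell (8 adjusted over the list alone), had a median of 3.66 (adjusted p = 4.39e-09). Its median turned to lower when foreign RNA was subtracted, which takes out that RNA by construction. None of these 8 lists passed with the correlation between genes taken from the data (smallest adjusted p = 0.816 with an estimated correlation). That form of the test has 1 residual degree of freedom here. Failing it, in any class or cluster, therefore does not show that a list is unchanged. Passing with the preset correlation, in any class or cluster, rests on the spread over genes and not on that between libraries. Such a pass does not show that a shift exceeds the variation between libraries.

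Hormone response lists did not pass as sets in luminal cells. Of 47 androgen-responsive genes 1 fell and none rose, Gucy1a1 by 2.68 ± 0.64 (4 adjusted over the list alone; median -0.14, adjusted p = 0.147). The 36 estrogen-responsive genes had a median of -0.00 (adjusted p = 0.978), with Pgr higher and Tff3 and Pdzk1 lower (4 adjusted over the list alone). The 25 steroid enzyme and receptor genes had a median of -0.10 (adjusted p = 0.486), with Pgr as the gene that rose (2 adjusted over the list alone). NF-kB and inflammation genes had a median of -0.38 (adjusted p = 0.0619) with Ccl2 lower (2 of 26 adjusted over the list alone), and the list passed in 5 other settings. In the dissociation stress list Hspa1a rose and Jund fell, while the median of -0.02 and the test (adjusted p = 0.697) differed in sign. The extracellular matrix list had Timp2 lower (median -0.19, adjusted p = 0.903; 1 of 31 adjusted over the list alone). None of the genes passed in the unfolded protein response (median 0.10), MHC class I (-0.05), MHC class II (0.27), apoptosis and survival (-0.07), fatty acid synthesis (-0.26), polyamine metabolism (0.03), oxidative phosphorylation (-0.04), glycolysis and hypoxia (0.01) or stromal paracrine factor (-0.23) lists, with adjusted p from 0.158 to 0.978.

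**Figure D4:**
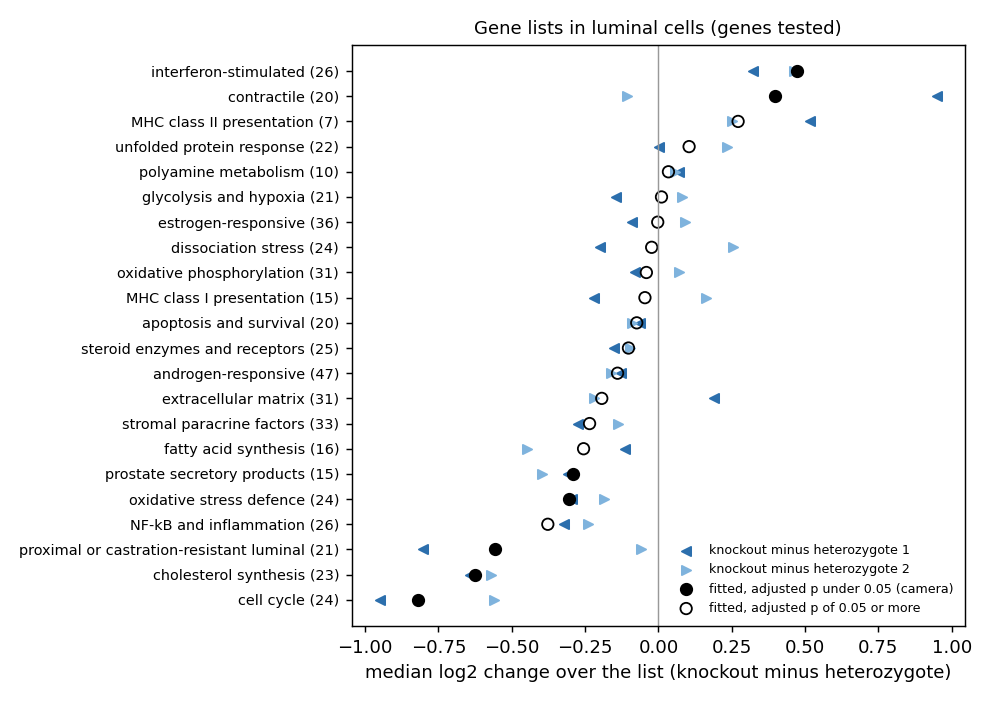
Median log2 change of each gene list in luminal cells (x axis), with points for the fitted value and for the knockout against each heterozygote. Cell cycle (-0.82) and cholesterol synthesis (-0.62) lay lowest and interferon-stimulated genes (0.47) highest. The seminal vesicle list (3.66) is not drawn.

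Proximal luminal cells, the Psca- and Krt4-bearing cells near the urethra, were a smaller share of all knockout cells, but as a share of luminal cells they did not differ beyond the spread between heterozygotes. They made up 6.74% of knockout luminal cells (exact 95% interval 5.61 to 8.01%) against 13.9% (12.5 to 15.3%) and 5.34% (4.73 to 5.997%). The knockout minus heterozygote gap was -2.87 percentage points, and 1.40 with heterozygote 1 left out. Among secretory cells, knockout cells sat mostly in cluster 2 (586 of 1752 luminal cells, against 560 of 2480 and 672 of 4967, led by Scin, Banf2 and Ren1) and cluster 6 (343, led by Acacb and Tbc1d4, of low depth). Heterozygote cells sat more in cluster 3 (622 and 841 against 206 in the knockout, led by Gpx3 and Ms4a5). Cluster 4, led by Ren1 and C1s2, held 313, 287 and 910 cells, a knockout share between those of the heterozygotes.

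Cholesterol synthesis transcripts were lower in knockout basal cells. Idi1 and Fdps, enzymes of the mevalonate pathway, fell by 1.90 ± 0.28 (adjusted p = 3.09e-09) and 2.40 ± 0.39 (adjusted p = 3.04e-07), and 6 of 21 list genes fell and none rose (10 adjusted over the list alone; median -0.77, adjusted p = 1.16e-09), a list call that ended with an estimated correlation (adjusted p = 0.566). Bmp5, a growth factor of the bone morphogenetic family, rose by 4.32 ± 0.51 (105 UMIs against 2 and 4; adjusted p = 2.37e-14), and the estrogen-induced Rerg rose by 1.86 ± 0.25 (adjusted p = 4.62e-11). Pbsn fell by 1.28 ± 0.32 (adjusted p = 0.00511), though it was only 0.25 below heterozygote 1. That call ended with DESeq2, with doublets kept and with the stricter cell filter. Also lower were Prol1 at -2.49 ± 0.29, Spink5 at -2.58 ± 0.34 and Inmt at -2.38 ± 0.31, and Sim2 was at least 7.83-fold lower. Prol1 is the first leading gene of proximal cluster 28 and was called lower in luminal cells, fibroblasts and macrophages as well. Spink5 is the first leading gene of secretory cluster 16. Luminal RNA was not tested gene by gene as a source of these basal decreases, and RNA of cluster 28 was not among the RNA subtracted. Ceacam10 rose by 6.97 ± 0.33 (adjusted p = 2.05e-93), Scgb1b27 was 105-fold higher (28.7 to 875), Dnase2b 43.2-fold higher (11.6 to 363) and the lectin Reg3g at least 8.86-fold higher. In total 296 of 11522 genes differed (125 higher, 171 lower), against none with heterozygote 1 or 2 as the lone library (193 and 739 at an unadjusted p under 0.05, where the knockout had 1202). DESeq2 called 34 genes and the stricter cell filter left 190.

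Contractile genes rose in basal cells, where Tagln (1.54 ± 0.25, adjusted p = 1.79e-07) and Acta2 (1.25 ± 0.24, adjusted p = 5.29e-05) led 8 of 20 that rose (11 adjusted over the list alone; median 0.85, adjusted p = 2.13e-05). These are smooth muscle genes, smooth muscle was 6.65% of knockout cells against 2.89% and 2.12%, and RNA from smooth muscle was not among the RNA subtracted. The MHC class II list was higher in basal cells through Cd74 (1.39 ± 0.38; 82 UMIs against 16 and 20), 1 of 6 genes (4 adjusted over the list alone; median 1.54, adjusted p = 6.05e-06). In the same knockout cells 5 macrophage genes reached 104% of the UMIs that macrophage RNA would bring with these class II UMIs. Of 20 interferon-stimulated genes Stat2 rose (2 adjusted over the list alone; median 0.62, adjusted p = 5.28e-05), and of 21 extracellular matrix genes Col12a1 and Fn1 rose (7 adjusted over the list alone; median 0.15, adjusted p = 0.0137). The extracellular matrix median differed in sign between the comparisons with each heterozygote. Oxidative stress defence fell through Gstp1, Gsta3, Gclc and Gclm (4 of 23, and 4 adjusted over the list alone; median -0.37, adjusted p = 4.13e-04). The proximal list had 1 gene higher and 4 lower of 18 (9 adjusted over the list alone; median -0.39, adjusted p = 0.0221). Prostate secretory products went mostly down, 11 of 14 against 2 up (13 adjusted over the list alone; median -1.64, adjusted p = 2.78e-04), and all 10 seminal vesicle genes rose (10 adjusted over the list alone; median 5.35, adjusted p = 3.33e-17). Luminal RNA was estimated at 3.24% of knockout basal UMIs against 3.801% and 13.4%. Most knockout luminal Scgb1b27 UMIs came from a few cells, whose RNA was not tested as the source of that gene in basal cells. Subtracting foreign RNA left 84 of the 296 calls, ended the interferon and extracellular matrix list calls and the Pbsn, Dnase2b and Reg3g calls, and turned the secretory list to a median of 1.28. None of the 9 lists passed with an estimated correlation (smallest adjusted p = 0.566 with an estimated correlation).

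Knockout fibroblasts carried more inflammatory chemokine transcript and less Tslp. Cxcl9, an interferon-induced T cell attractant, was at least 22.8-fold higher (149 UMIs against none), and the acute phase protein Saa3 at least 13.5-fold higher (88 against none). The epithelial cytokine Tslp fell by 4.33 ± 0.54 (adjusted p = 7.11e-13), the complement component C7 by 3.31 ± 0.46 (adjusted p = 2.45e-10), the mesenchymal transcription factor Osr1 by 3.17 ± 0.48 (adjusted p = 1.36e-08) and the relaxin receptor Rxfp1 by 3.30 ± 0.89 (adjusted p = 0.0173). Ptgs2 (2.15 ± 0.37) and Cxcl1 (2.23 ± 0.39) rose as well, and with Saa3 made up the 3 of 20 NF-kB and inflammation genes that rose; Cebpb fell against heterozygote 2 (-2.66) and not against heterozygote 1 (0.57). That list had a median of 0.39 (4 adjusted over the list alone; adjusted p = 0.00161). Of 17 interferon-stimulated genes Iigp1 and Gbp2 rose (4 adjusted over the list alone; median 0.55, adjusted p = 1.2e-04). The 24 dissociation stress genes (median 0.30, adjusted p = 0.00419; none adjusted over the list alone) and 29 extracellular matrix genes (median 0.35, adjusted p = 0.0377; 1 adjusted over the list alone) were higher as sets with no gene past the threshold. None of these lists passed with an estimated correlation (smallest adjusted p = 0.834). Pgr was at 1.99 ± 0.64 (adjusted p = 0.0906), on 58 UMIs against 6 and 1, with 0.70 against heterozygote 1 and 3.14 against heterozygote 2.

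Of 7275 genes tested in fibroblasts, 109 differed (40 higher, 69 lower), but 26 and 65 passed with heterozygote 1 or 2 as the lone library, and heterozygote 1 had 63 fibroblasts. Scgb1b27 (at least 12.6-fold higher), Scgb2b27 (at least 7.66-fold higher) and Ceacam10 (3.53 ± 0.48) rose beside 5 of 10 seminal vesicle genes (5 adjusted over the list alone; median 1.63, adjusted p = 2.82e-15), and of 13 prostate secretory products 5 fell and 1 rose (9 adjusted over the list alone; median -1.69, adjusted p = 0.00277). Luminal RNA was estimated at 3.26% against 3.02% and 15.5%, so the secretory list followed heterozygote 2, with medians of -0.15 against heterozygote 1 and -2.28 against heterozygote 2. Most knockout luminal UMIs of Scgb1b27 and Scgb2b27 came from a few cells, whose RNA was not tested as their source in fibroblasts. After foreign RNA was subtracted 7 genes passed, Cxcl9, Srd5a2, Tslp, C7 and Osr1 among them, and the extracellular matrix and secretory list calls ended. Subtraction also turned Ceacam10 and the seminal vesicle list to lower. Before it, Ceacam10 was 2.44 above heterozygote 1 and 7.67 above heterozygote 2. The extracellular matrix call also ended with another random seed for the clustering. With limma-voom Cxcl9, Saa3 and Rxfp1 did not pass, nor did Tslp and Rxfp1 with the stricter cell filter. The seminal vesicle and secretory lists did not pass with an estimated correlation either.

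Smooth muscle gained Tnnt2, the cardiac form of troponin T, by 4.05 ± 0.26 (adjusted p = 0.0497; 526 CPM against 37.0 and 27.5). The other 5 of 6 genes that passed, of 9051 tested, were Svs1, Svs3a, Svs3b, Svs6 and Ceacam10 (6.37 ± 0.30). Large differences that did not pass were Edn1, the vasoconstrictor endothelin (3.48 ± 0.42, adjusted p = 0.314), Kctd16 (2.86), Synpr (24.5-fold higher, 6.595 to 205), Coch (-2.78 ± 0.26, adjusted p = 0.161), the tendon protein tenomodulin Tnmd (-2.53 ± 0.24, adjusted p = 0.161), Gstp1 (-2.48) and Ptgds (-2.57). The count depended on the setting: 171 genes passed with median-ratio scaling, 42.7% of them higher, 39 with DESeq2 and 344 with limma-voom, and 796 had an unadjusted p under 0.05. With another random seed or arithmetic kernel for the clustering, which changed the class from 597, 130 and 201 cells to 595, 131 and 201 or 598, 131 and 201, 337 and 324 passed. Coch, Tnmd, Edn1, Kctd16, Synpr, Gstp1 and Ptgds passed in both. With heterozygote 1 or 2 as the lone library 4 and 0 genes passed with edgeR (243 and 352 at an unadjusted p under 0.05).

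As sets, smooth muscle genes for interferon response (17 genes, median -0.66, adjusted p = 0.00708), MHC class I (14 genes, median -0.37, adjusted p = 0.00708) and NF-kB and inflammation (19 genes, median -0.29, adjusted p = 0.0316) lay lower, with none past the threshold singly or adjusted over the list alone. Contractile genes lay higher (20 genes, median 0.30, adjusted p = 0.0168; none adjusted over the list alone) and oxidative stress defence lower (23 genes, median -0.26, adjusted p = 0.0238; 4 adjusted over the list alone). Prostate secretory products lay lower (14 genes, median -1.66, adjusted p = 7.38e-04; 4 adjusted over the list alone) and the seminal vesicle list higher (4 of 10 rose, 5 adjusted over the list alone; median 4.56, adjusted p = 7.74e-10). Luminal RNA was estimated at 1.94% of knockout UMIs against 2.58% and 7.37%, and the secretory and contractile calls ended when foreign RNA was subtracted. None of the 7 lists passed with an estimated correlation (smallest adjusted p = 0.788 with an estimated correlation).

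Endothelial cells, a class whose borders moved with the clustering, lost the fatty acid carrier Fabp4 (-3.57 ± 0.55, adjusted p = 5.22e-08), a gene of capillary endothelium, and the flow-induced transcription factor Klf2 (-2.82 ± 0.54, adjusted p = 5.59e-05). The Klf2 decrease was not particular to them, as it was also called in luminal cells (-1.58), basal cells (-1.81) and macrophages (-2.36). Cxcl9 was 35.9-fold lower (11.8 to 179), opposite to fibroblasts, Cytl1 at least 37.0-fold lower, and the elastin gene Eln fell by 2.24 ± 0.59 (adjusted p = 0.0264). Wfdc3 rose by 3.23 ± 0.47 (adjusted p = 4.79e-09), and Dnase2b (59.1-fold, 10.4 to 2359), Epha3 (36.2-fold, 6.25 to 1453), Ivl (at least 8.45-fold) and Ceacam10 (7.16 ± 0.51) were higher. Penk fell by 3.45 ± 0.68. Of 6739 genes 49 differed (30 higher, 19 lower), against 0 and 7 with heterozygote 1 or 2 as the lone library (118 and 777 at an unadjusted p under 0.05, where the knockout had 334). Wfdc3 turned to lower (-1.56) at Leiden resolutions 0.5 and 2.0, where 127, 71 and 105 endothelial cells were left, and with the stricter cell filter (-1.42), and most named genes did not pass with DESeq2 or limma-voom, while Klf2 and Fabp4 kept their call. Another random seed or arithmetic kernel for the clustering left 127, 70 and 105 or 127, 71 and 105 of the 341, 92 and 127 cells. The counts were then 52 and 51 genes, 17 of the 49 among them each time, with 30.8% and 29.4% higher against 61.2% here. Fabp4, Klf2, Cytl1, Cxcl9 and Penk kept their call, Wfdc3 was lower (-1.52 and -1.56), and Dnase2b, Epha3 and Ivl were too low to be tested. Foreign RNA was heavy in this class, with 20.4%, 17.8% and 2.31% of UMIs from the seminal vesicle list and luminal RNA estimated at 23.3%, 7.98% and 17.3%.

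List results in endothelial cells held only for the clustering used here, apart from the seminal vesicle list. Interferon-stimulated genes lay lower in the knockout (25 genes, median -0.60, adjusted p = 1.32e-05; none past the threshold or adjusted over the list alone) and unfolded protein response genes higher (22 genes, median 0.59, adjusted p = 5.82e-07; 2 adjusted over the list alone). Extracellular matrix genes were lower (Eln 1 of 16 that fell, 3 adjusted over the list alone; median -0.44, adjusted p = 0.0017), as were 9 stromal paracrine genes (median -0.65, adjusted p = 0.0394; none adjusted over the list alone), and both calls ended when foreign RNA was subtracted. Of 14 prostate secretory products 3 rose and 1 fell (4 adjusted over the list alone; median 0.45, adjusted p = 0.00136), and of 10 seminal vesicle genes 6 rose (8 adjusted over the list alone; median 5.52, adjusted p = 7.81e-40). With another random seed or arithmetic kernel for the clustering, the interferon-stimulated, unfolded protein response, extracellular matrix and stromal paracrine calls ended, the secretory list fell (medians -1.33 and -1.31), and the seminal vesicle list stayed higher (4.34 and 4.37). None of the 6 lists passed with an estimated correlation (smallest adjusted p = 0.91 with an estimated correlation).

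A few interferon-induced genes and fibronectin were lower in knockout macrophages. Ifit1 fell by 3.25 ± 0.48 (adjusted p = 6.67e-09), Isg15 by 1.59 ± 0.38 and Rsad2 by 1.60 ± 0.39, all interferon-induced, although the interferon-stimulated list of 20 genes did not move as a set (median -0.07, adjusted p = 0.248). Fibronectin (Fn1) fell by 4.17 ± 0.58 (adjusted p = 3.3e-10), Prkg1 by 2.26 ± 0.50, Ralgapa2 by 3.18 ± 0.91, and Cbr2, a marker of resident macrophages, was 18.7-fold lower (4.69 to 162). Cxcl9 rose by 2.07 ± 0.42 (adjusted p = 2.02e-04), Qsox1 by 2.11 ± 0.57, Myo9a by 1.83 ± 0.51 and Ceacam10 by 6.55 ± 0.45. Of 5260 genes 70 differed (29 higher, 41 lower), against 10 and 39 with heterozygote 1 or 2 as the lone library, from 163, 54 and 122 cells. With DESeq2 12 passed, 58.3% of them higher, and with limma-voom 1, where Ifit1, Fn1, Prkg1, Ralgapa2, Cbr2, Cxcl9, Qsox1, Myo9a and Ceacam10 did not pass.

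Contractile genes were higher in knockout macrophages, 4 of 14 (5 adjusted over the list alone; median 1.29, adjusted p = 1.31e-05), led by Tagln (2.19 ± 0.46) and Myh11 (2.34 ± 0.58), with Cald1 at 2.27 ± 0.63. These too are smooth muscle genes, in a library with the larger smooth muscle share (6.65% against 2.89% and 2.12%), and smooth muscle RNA was not subtracted. Oxidative stress defence was lower through heme oxygenase Hmox1 (-1.56 ± 0.37), 1 of 18 genes (4 adjusted over the list alone; median -0.47, adjusted p = 2.59e-04). The 7 cell cycle genes tested were lower as a set (median -0.55, adjusted p = 0.00679; none adjusted over the list alone). All 10 seminal vesicle genes rose (10 adjusted over the list alone), with a median of 5.90, or 5.23 with genes at 0 set to their bound (adjusted p = 4.41e-31). None of the 4 lists passed with an estimated correlation (smallest adjusted p = 0.954 with an estimated correlation).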

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

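Tests on Ceacam10, Dnase2b and 9530003J23Rik and on Rrp1b were chosen only after the result was seen, while those on the whole gene set and on the secretoglobins were written before. Barcodes under 500 genes, kept only in part under the looser filter and otherwise used to pick genes left out of clustering, carried a strong seminal vesicle signal in the knockout, where the seminal vesicle list took 26.3% of UMIs (95% interval 26.2 to 26.4%; 2521 barcodes) against 4.23% in heterozygote 2 (2249 barcodes). Heterozygote 1 held only 2 such barcodes, with 36.2%, and is too thin to compare.

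RNA from seminal vesicle-like cells of the same library was weighed as the source of genes higher in the knockout in at least 3 classes. For these 9 genes, 45.5% of 33 gene and class pairs had knockout UMIs within 2-fold of the amount predicted from the seminal vesicle list, so for the set as a whole that RNA and regulation cannot be told apart, because its members split. Ceacam10, Dnase2b and 9530003J23Rik lay within 2-fold in 100% of 13 pairs, but they were set apart because of those values, so the figure does not bear on their source. The tables argue against that source for Scgb1b27 and Scgb2b27 in luminal cells, at 1516 and 1502 times the prediction. They also argue against it for Rrp1b, at 11 to 144 times. Rrp1b lies on chromosome 17, as Srd5a2 does, and a strain difference around the targeted allele stays open for it. Rrp1b was also the first leading gene of unnamed cluster 7 (median 2151.5 UMIs). RNA of that cluster was not weighed as a source. Whether the surplus of seminal vesicle RNA goes with the genotype, with how much adjoining gland was dissected, or with the single knockout library stays open.

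Several results went opposite ways in different cell classes, with each heterozygote on the same side within a class; none of these differences between classes was tested. The matrix protein Fn1 was higher in basal cells (1.25) and lower in macrophages (-4.17), a gap of 5.42 on the log2 scale. The chemokine Cxcl9 was higher in fibroblasts, by at least 4.51 against the floor, and lower in endothelial cells (-5.17, from 3 knockout UMIs), a gap of 9.68 with the fibroblast part at its bound and the endothelial part an imprecise ratio. Wfdc3 was higher in endothelial cells (3.23) and lower in basal cells (-2.83), a gap of 6.07. List medians parted by 1.28 for interferon-stimulated genes between basal cells (0.62) and smooth muscle (-0.66). They parted by 0.686 for NF-kB and inflammation between fibroblasts (0.39) and smooth muscle (-0.29), and by 0.785 for extracellular matrix between fibroblasts (0.35) and endothelial cells (-0.44). Prostate secretory products parted by 2.14 between endothelial cells (0.45) and fibroblasts (-1.69). Wfdc3 is a leading gene of luminal cluster 14. Luminal RNA was estimated at 23.3%, 7.98% and 17.3% in endothelial cells, 3.24%, 3.801% and 13.4% in basal cells, and 3.26%, 3.02% and 15.5% in fibroblasts (knockout, heterozygote 1, heterozygote 2). For Wfdc3 and the secretory list, luminal RNA and a change in the cells themselves cannot be told apart. The endothelial side of these gaps depended on the clustering: with another random seed Wfdc3 in endothelial cells was lower (-1.52), the secretory list in endothelial cells was lower (-1.33) and the extracellular matrix call ended, while Cxcl9 kept its call.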

How the results depend on the processing

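Leiden resolutions for genes changed, another random seed, another arithmetic kernel, cells of matched depth, the subtraction of foreign RNA and the luminal clusters low in seminal vesicle RNA were chosen after seeing the data, as were shares without cluster 9, tests in single clusters, list tests on thinned counts and the second luminal ranking; the cause was not tested for any change unless stated. The Esr1 fold change stayed on its side of the threshold in all 14 settings, and 8 to 12 classes stayed outside both heterozygotes. Single genes were the same in 1177 comparisons, with 106 now passing, 103 no longer passing, 99 moved and 15 reversed; list medians were the same in 437, with 11 now passing, 65 no longer passing, 6 moved and 11 reversed. Cluster borders moved with the seed and with the last digits of the neighbor distances, which depend on the arithmetic kernel; the results given are those of the clustering made at the start. Genes called in luminal cells (232) became 538 with median-ratio factors, 142 with DESeq2, 519 without a low-count filter, 474 thinned, 535 after subtraction, 396 at Leiden 0.5, 357 with another kernel, 501 in secretory clusters and 394 in clusters low in seminal vesicle RNA; the other settings gave 203 to 346. Basal calls (296) became 34 with DESeq2, 190 with the stricter filter, 196 thinned and 87 after subtraction. Fibroblast calls (109) became 11 with DESeq2, 333 with doublets kept, 56 thinned and 7 after subtraction. Smooth muscle calls (6) became 171 with median-ratio factors, 39 with DESeq2, 288 without the filter, 344 with limma-voom, 253 with doublets kept, 138 and 322 with the looser and stricter filters, 190 thinned, 254 after subtraction, 11 and 324 at Leiden 0.5 and 2.0, and 337 and 324 with another seed and kernel. Endothelial calls (49) became 18 with median-ratio factors, 9 with DESeq2, 119 with doublets kept, 84 with the looser filter and 75 after subtraction. Macrophage calls (70) became 12 with DESeq2, 1 with limma-voom and 44 thinned; with doublets kept, and at Leiden 2.0 or with another seed, heterozygote 1 had 31 and 28 macrophages, under 50, so no value was had. Thinning leaves fewer UMIs by construction. The knockout difference in the share of luminal cells with an Esr1 UMI (3.36 percentage points) became 0.799 with doublets kept, 1.23 and 1.64 with the looser and stricter filters, 2.76 and 1.20 at Leiden 0.5 and 2.0, 0.462 and 2.65 with another seed and kernel, 6.43 unthinned and 3.61 in clusters low in seminal vesicle RNA. That in the proximal share of luminal cells (-2.87) ran from -7.14 to 1.40 with 1 heterozygote left out. The number of luminal lists past the threshold (8) became 0 with an estimated correlation and 6 to 9 elsewhere. With an estimated correlation the test has 1 residual degree of freedom, so a list could hardly pass. Reversed in proximal clusters alone were Itpripl2 (-0.59), Nupr1 (0.56) and Creb3l1 (0.71). Subtraction reversed Svs3b in luminal cells (-11.44), Svs3a in luminal cells (-11.83), Sva in luminal cells (-12.29), Ceacam10 in luminal cells (-13.59), Ceacam10 in fibroblast cells (-8.88), the seminal vesicle list in luminal cells (-6.26) and fibroblasts (-3.85), and the prostate secretory list in basal (1.28) and endothelial cells (-0.0562); it takes out that RNA by construction. Scgb2b27 reversed with the stricter filter (-2.27) and in secretory clusters (-2.05), and Wfdc3 in endothelial cells with the stricter filter (-1.42) and at Leiden 0.5 and 2.0 and with another kernel (each -1.56) and seed (-1.52). Another seed and kernel also reversed the prostate secretory list in endothelial cells (-1.33 and -1.31) and the interferon-stimulated list in endothelial cells (0.00864 and 0.0299). The luminal contractile median reversed with the looser filter (-0.0768) and ran from -0.11 to 0.95 with 1 heterozygote left out; the basal extracellular matrix median ran from -0.0818 to 0.30. At these depths simulated changes of a log2 size of 1 were recovered in 59.7% (fibroblasts) and 65.7% (macrophages) against 65.7% in the far deeper luminal class. The simulated changes were placed only in genes well counted in each class, so this cannot show whether depth limited the calls. Fewer genes could be tested in fibroblasts (7275) and macrophages (5260) than in luminal cells (17153). Srd5a2 outside the stroma had few UMIs. No paired analysis was possible because replicate numbers only name samples and the groups share fewer than 2 numbers.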

Other observations

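Knockout cells in seminal vesicle-like clusters 5 and 13 carried an interferon and antigen presentation signature. These clusters hold cells of all 3 libraries and were tested only after the data were seen. Seminal vesicle-like clusters 9, 11 and 22, with 879, 802 and 136 knockout cells, were not tested. Clusters 5 and 13 were not tested under another clustering. In cluster 13 (309, 325 and 132 cells; led by Sprr2f, Wfdc15b and Folr1), the interferon-induced GTPase Iigp1 rose by 6.30 ± 0.43 (adjusted p = 3.39e-13), Gbp2 by 4.14 ± 0.38 and the antiviral Ifit3 by 4.41 ± 0.41. Of 26 interferon-stimulated genes 22 rose and none fell (25 adjusted over the list alone; median 3.11, adjusted p = 8.44e-39), and all 26 were above both heterozygotes. The MHC class II chain H2-Ab1 rose by 5.36 ± 0.43 (adjusted p = 3.11e-11) and its chaperone Cd74 by 4.10 ± 0.37, with 6 of 7 list genes up (6 adjusted over the list alone; median 4.10, adjusted p = 5.43e-13). MHC class I genes rose less, Psmb8 by 2.07 ± 0.35 (6 of 15, and 7 adjusted over the list alone; median 0.78, adjusted p = 4.2e-07). Androgen-responsive genes were lower, with 5 that fell and 2 that rose of 41 (10 adjusted over the list alone; median -0.40, adjusted p = 0.0176), Fkbp5 by 1.86 ± 0.42 among them. The desaturase Fads2 fell by 2.72 ± 0.50 within the fatty acid synthesis list (6 of 16 adjusted over the list alone; median -0.74, adjusted p = 6.7e-04), and cholesterol synthesis had a median of -0.76 (2 of 22 adjusted over the list alone; adjusted p = 3.62e-04). None of these lists passed with an estimated correlation (smallest adjusted p = 0.655 with an estimated correlation). Of 9945 genes 330 differed (138 higher, 192 lower).

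Cluster 5 (490, 298 and 483 cells; led by Pate8, Ccdc162 and Pate4) also had higher MHC class II and interferon-stimulated transcripts; it was not compared with cluster 13 by a test. Cd74 rose by 3.59 ± 0.36 (adjusted p = 3.61e-20) and H2-Ab1 by 4.24 ± 0.48 (adjusted p = 1.83e-15), with 3 of 6 class II genes up (3 adjusted over the list alone; median 1.92, adjusted p = 1.03e-07). Of 20 interferon-stimulated genes 9 rose and none fell (12 adjusted over the list alone; median 1.22, adjusted p = 4.85e-16), Ifit1 by 3.63 ± 0.73 and Rtp4 by 1.21 ± 0.28. Cholesterol synthesis genes had a median of -0.48 (adjusted p = 8.09e-04) with none past the threshold. None of these 3 lists passed with an estimated correlation (smallest adjusted p = 0.776 with an estimated correlation). Of 11556 genes 266 differed (103 higher, 163 lower).

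Tests on each of cluster 13, cluster 5 and basal cells alone, and every test on the cholesterol and cell cycle lists, were chosen only after the result was seen; the joint macrophage test and the test for a few cells were written before. For MHC class II, RNA from macrophages of the same library was weighed by whether C1qa, C1qb, C1qc, Lyz2 and Tyrobp reach the UMIs that the class II genes predict; over the 3 groups they reached from 3.02% to 104%, so no single answer held for all. In cluster 13 they reached 3.02% (13 UMIs of 429.8 predicted), which argues against macrophage RNA there. In basal cells they reached 104% (39 UMIs against 37.6), in line with macrophage RNA as the source of the basal signal, and in cluster 5 34.7%, between the bounds set. A few cells of another type within cluster 13 stay possible, since 10 cells held 44.4% of 2298 class II UMIs, although 173 of 309 knockout cells (56.0%) had such a UMI against 27 of 325 (8.31%) and 19 of 132 (14.4%). A response of knockout seminal vesicle epithelium to interferon, next to the larger share of T or NK cells, is a candidate explanation for cluster 13 that was not tested, and genotype and library stay confounded.

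Lower cholesterol synthesis and cell cycle transcripts in luminal cells were weighed against 3 technical explanations. A different mix of clusters 2, 3, 4, 14 and 16 is argued against by single clusters, where both medians lay under -0.2 in 5 of 5. Cluster 6, a secretory cluster outside that test, had medians of -1.34 for cholesterol synthesis and -0.15 for the 6 cell cycle genes tested, proximal cluster 15 had 0.53 and -0.03, and clusters 19 and 23 had too few knockout cells, so the mix of those clusters stays open as a part of the cell cycle change. Dilution by RNA from seminal vesicle-like cells is argued against by its size, an estimated 5.14% of knockout luminal UMIs against 1.18% and 3.26%. So small a share could not lower other genes this far, and its subtraction left medians of -0.61 and -0.80. Counts thinned to equal class totals gave medians of -0.59 and -0.87. Such thinning keeps each gene's expected share of UMIs, so it could not test a difference in depth. Neither list passed with an estimated correlation (adjusted p = 0.816), a form of the test with 1 residual degree of freedom that cannot decide. Depth per cell and a property of the single knockout library stay open.

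Of the ribosomal protein genes tested in all 6 classes, 23 were higher and 5 lower than both heterozygotes in each class. The other 47 were not on the same side of both heterozygotes in every class. Some of these still had a single fitted direction, such as Rpl28 (0.04 to 0.58) and Rps27 (-0.24 to -0.82), and others did not. The classes come from the same 3 libraries, so agreement between them is not independent, and how many genes would agree by chance was not estimated. Rpl24 was 0.94 to 1.503 higher and Rps2 0.49 to 1.30 higher, while Rpl9 lay between -0.84 and -1.32 and Rpl15 between -0.19 and -1.67. The transcription factor Jund was lower in each of the 6 classes, from -1.23 to -1.66, and passed in luminal and basal cells.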
